A study of Macaca fascicularis with 18 samples.

How the data were processed

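Whole-lung total RNA was measured in 18 samples of cynomolgus macaques: 2 baseline controls, 8 samples of low-dose challenge, 4 of high-dose challenge and 4 of sepsis-induced death, grouped by the source name in the labels. Per the labels' protocols RNA was extracted with TRIzol and libraries were made with a TruSeq kit with ribosomal RNA removal (Ribo-Zero). Bowtie 0.12.8, TopHat2 2.0.6, TopHat, CASAVA and bedtools 2.17.0 are named, with no role, per the submitters' processing notes. The genome build, the counting rule and any filter were not given in the sources used here. Replicate numbers were assigned in accession order and only name samples. A column name of high dose replicate 3 differed from its sample's title in 1 digit of the animal code and was matched by the rest of the name.

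The authors deposited log2 values, 1 per gene and library. The values themselves gave the scale: 2 to the power of the value, less 1, was a whole multiple of the worth of 1 read in 100% of values of every library, within 0.05 of a read, and these numbers summed to 990321 to 997933 per library. The deposited values were therefore read as log2(RPM + 1), with RPM the reads of a gene scaled to the library's total, an inference from the numbers. The worth of 1 read gave totals of 3.52 to 11.35 M reads per library (median 6.88 M). The genes sum to nearly these totals although overlapping genes share reads. The totals may therefore be sums of counts over genes, with some reads counted more than once, and not the reads sequenced. Fold changes on this scale understate the change of genes with few reads. Of the 17476 genes tested, 2879 had no name in the file and 782 carried a protein entry name, 58 of which were paired by hand with a gene symbol; 10164 had a usable symbol. Names turned into dates (13), damaged chromosome names (521) and blank ones (656) were not repaired, and identifiers of the file are those of rhesus macaque genes. Of the genes with a blank chromosome name, 23 lying between positions 536 and 15881 were taken as the mitochondrial loci. That is an inference from their positions, on which all mitochondrial shares below rest. Reads had been counted over whole gene spans: in all 1650 pairs with a gene nested in another, the host gene had at least as many reads. Of the genes, 3584 overlapped another, and 2687 had overlapping genes with at least 0.5 of their RPM, so their reads cannot be told apart. Named genes of that kind are given as uncertain. A table of gene names that came with the reference was not used for coordinates.

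All 18 libraries entered 1 linear model with 4 group means and a shared spread, fitted with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend). The design had set out a different test for each unit that the values could have had, and the branch for log values was used, on the values as deposited with no added pseudocount. No filter on low values removed a gene, since the lowest gene mean was 0.79 and each gene was above 0 in at least 10 libraries. Contrasts of group means were two-sided, with Benjamini-Hochberg adjustment over all genes within a comparison and a threshold of 0.05. Of 43 gene lists fixed before the data were examined, 42 had at least 4 measured members and were tested with camera (preset correlation 0.01), with adjustment over the lists of a comparison. The list of genes encoded by mitochondria had 0 measured members. It was fixed as a measure of sample quality, as were the lists of immediate early genes and cytosolic ribosomal proteins. No list kept its call with an estimated correlation in camera, and fry, which asks whether genes of a list move on balance in 1 direction, was run beside it. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment within the list. Library measures were compared by exact permutation tests, and the relation between 2 genes and a mitochondrial locus by permutation tests, over all libraries and within groups.

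The rule for named genes was set before the data were examined. For each comparison it takes, among genes past the threshold that have a symbol, a mean above the median gene and no overlap between the groups, the 6 largest rises and the 6 largest falls. From each list that was called or held at least 3 genes past the threshold it takes up to 4 members with the smallest p. The rule took 99 genes for sepsis death against control, 123 against low dose and 82 against high dose, 42 for high against low dose, 60 for low dose against control and 28 for high dose against control. The text gives 43, 50, 38, 24, 14 and 12 of these. The 6 largest rises and falls are given except for results not reported here, and the members of the lists were thinned to 0 to 4 per list after their values and their stability had been seen, so the named genes keep their calls far more often than the rest of the genes the rule takes. With each library left out in turn, 48 of the 50 named called genes and 2 of the 43 others passed in all fits for sepsis death against low dose, and 36 of 38 and 10 of 39 against high dose. For sepsis death against control and for high against low dose 0 passed in all fits in either set.

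The alternatives set before the data were examined were median centring, quantile normalisation, a filter at the lower quartile of gene means, limma without a trend, array weights, a fit of the compared groups alone, each library left out in turn, an estimated correlation, and fry. Chosen after seeing the data were voom (limma) on the recovered reads, a fit without both libraries of low ribosomal protein values, totals without mitochondrial and small RNA loci, genes with under 0.5 of their reads in overlapping genes, and library numbers 16 to 18 as a block. Scripts were tested on simulated data with 50 genes changed at each of 4 sizes among the 17476 genes. Changes went both ways, lay in genes above the median gene mean, and had a spread drawn independently for each gene. The shares recovered describe that setting and not the real data. At a log2 change of 2 the test recovered 92% of changed genes for sepsis death against low dose, 84% against high dose and 54% against control, 88% for high against low dose, 74% for low dose against control and 68% for high dose against control. At a log2 change of 1 it recovered 44%, 18%, 2%, 30%, 10% and 2% in the same order. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.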

Results

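Whole-lung RNA from 18 samples of cynomolgus macaques (Macaca fascicularis, an Old World monkey) was sequenced in an experiment on challenge with Escherichia coli. The labels put 2 samples in a baseline control group, 8 in a low-dose challenge group, 4 in a high-dose challenge group and 4 in a group with sepsis-induced death. They give no bacterial number, time of sampling or sex, nor the challenge that preceded sepsis death. Library numbers in the sample titles run from 8 to 15 in low dose, with no other group among them. Library order therefore cannot be told apart from the low-dose group in any comparison with it. Sample titles carry separate identifiers, but nothing states that each came from a separate animal, so the p-values below measure the spread between these samples. Expression of 17476 genes was given as log2(RPM + 1), where RPM is the number of reads scaled to the library's total, and all differences below are on that scale. Library totals inferred from the values were 3.52 to 11.35 M reads (median 6.88 M), and may count reads shared by genes more than once. Sepsis death replicate 3 had the lowest depth, against 8.41 to 9.10 M in the other sepsis death libraries.

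RNA composition differed between groups. Reads in mitochondrial loci made up 2.96% ± 3.3 (SD, n = 4) of the high-dose libraries and 11.5% ± 3.88 (SD, n = 8) of the low-dose libraries (two-sided exact permutation p = 0.004, adjusted p = 0.037 over 12 tests of library measures). Few loci carried most of this share. In low dose replicate 4 (13.96%) the most abundant one held 100035 RPM and another 37594, and in high dose replicate 3 (0.27%) they held 1859 and 362. The share is thus no measure of mitochondrial genes at large. Summed values of small RNA loci made up 22.7% ± 10.4 (SD, n = 4) of the high-dose and 9.70% ± 2.31 (SD, n = 8) of the low-dose libraries (exact permutation p = 0.0061, adjusted p = 0.037). Of 24 abundant loci of the small RNA U1, 14 had values within 2% of their median. The same reads may therefore have been counted at several loci. The small RNA share may thus overstate the percent of reads, and totals that leave out these loci carry the same limit. The other 10 tests, of these shares, the mean of 18 cytosolic ribosomal protein genes and the read totals between the challenge groups, had exact permutation adjusted p from 0.12 to 0.84. Among them was the mitochondrial share of sepsis death (8.1% to 15.29%) against high dose (0.27% to 7.75%), a difference of 9.01 with no overlap. Its exact permutation p of 0.029 (adjusted p = 0.12) is the lowest that its 70 splits allow, so not passing does not speak for equal shares. Ribosomal protein genes averaged 5.29 in high dose replicate 3 and 5.84 in low dose replicate 5, against 6.43 to 7.41 in the other libraries. The median gene was higher in low dose than in control by 0.19 and lower in high dose than in low dose (difference -0.19) and in sepsis death than in low dose (difference -0.18). Small falls against low dose are to be read against that shift.

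**Figure D1:**
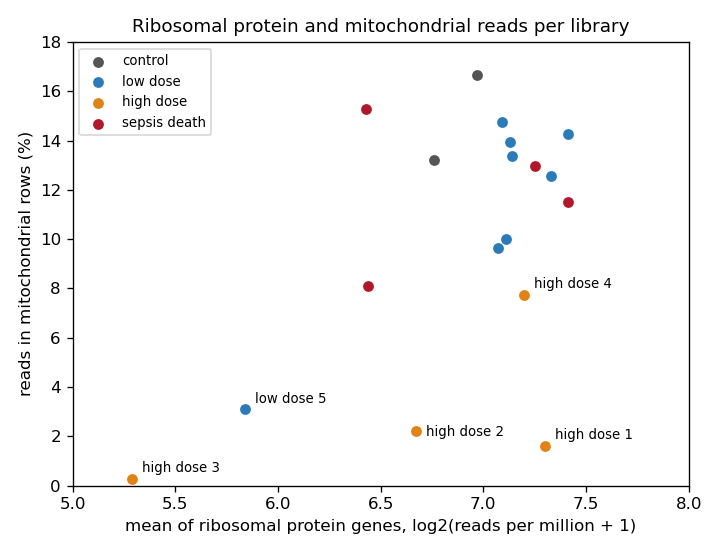
Mean of the ribosomal protein genes in log2(RPM + 1) (x axis) and percent of reads in mitochondrial loci (y axis), 1 point per library, coloured by group. High dose replicates 1 to 4 lie at 0.27% to 7.75% mitochondrial reads and low dose replicate 5 at 3.1%, below the other libraries, which lie at 8.1% to 16.68%.

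The comparison of sepsis death with low-dose challenge asked how the lungs of the samples labelled as sepsis death differed from the largest challenge group. Chemokine and cytokine genes rose. IL8, a neutrophil chemoattractant, averaged 7.91 ± 1.61 (SD, n = 4) in sepsis death and 1.87 ± 0.93 (SD, n = 8) in low dose, a difference of 6.04 (SE 0.58, adjusted p = 3.8e-05). CCL2, a monocyte chemoattractant, differed by 5.39 (SE 0.81), IL6 by 5.18 (SE 0.73) and CCL3 by 4.78 (SE 0.57), with adjusted p from 0.00018 to 0.001. LCN2, an iron-sequestering antibacterial protein, showed the largest rise among the abundant genes with no overlap between the groups, from 3.73 ± 1.57 (SD, n = 8) to 9.54 ± 1.28 (SD, n = 4), a difference of 5.82 (SE 0.85, adjusted p = 0.00082). It was followed by the haem oxygenase gene HMOX1 (difference 4.20, SE 0.73), the NF-kB inhibitor gene TNFAIP3 (3.81, SE 0.64) and the mitochondrial superoxide dismutase gene SOD2 (3.81, SE 0.60). The calprotectin subunit gene S100A8 (3.75, SE 0.72) and the nuclear receptor gene NR4A3 (3.63, SE 0.57) came next, and these genes had adjusted p from 0.0012 to 0.0041. NR4A3 averaged 6.04 in sepsis death, 6.03 in control and 2.41 in low dose. For this gene sepsis death thus lay at the control level and low dose below it.

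The largest fall by the same rule was in INMT, an indolethylamine methyltransferase abundant in lung. It went from 5.66 ± 0.71 (SD, n = 8) to 2.59 ± 0.19 (SD, n = 4), a difference of -3.07 (SE 0.36, adjusted p = 0.00018). FMO2, a flavin monooxygenase of lung (difference -3.0, SE 0.45), TEF, a PAR bZIP transcription factor (-2.56, SE 0.38), and DKK3 (-2.48, SE 0.50) followed. The basement membrane collagen gene COL4A4 fell too (-2.48, SE 0.29), as did the collagen prolyl hydroxylase gene P4HA2 (-2.39, SE 0.30). All had adjusted p of at most 0.005. The file places INMT on chromosome 3 from 95477554 to 95481365 and IL8 on chromosome 5 from 55942658 to 55945811, in a genome build not given in the sources used here.

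By list, 13 of 16 inflammatory cytokine and chemokine genes rose in sepsis death against low dose, over all genes tested and also when adjusted over the list alone (camera adjusted p = 2.83e-19; adjusted p = 0.051 with an estimated correlation). Of 17 NF-kB feedback and early response genes, 15 rose and 16 when adjusted over the list alone (adjusted p = 0.052 with an estimated correlation), among them TNIP3 (difference 3.75, SE 0.46) and ZC3H12A (2.86, SE 0.46), which restrain inflammatory signalling. Acute phase and iron handling genes rose in 8 of 11 cases, 10 when adjusted over the list alone (adjusted p = 0.051 with an estimated correlation). Neutrophil markers rose in 9 of 21 cases, 10 when adjusted over the list alone (adjusted p = 0.051 with an estimated correlation). The score of this list was 0.9 in low dose replicate 2, above the 0.65 of sepsis death replicate 2, and -0.87 to 0.15 in the other low-dose libraries. S100A9 went from 7.26 ± 1.14 (SD, n = 8) to 10.79 ± 0.07 (SD, n = 4) and the formyl peptide receptor gene FPR2 rose by 2.41 (SE 0.42). Of 15 genes of the unfolded protein and integrated stress response, 12 rose and 13 when adjusted over the list alone (adjusted p = 0.051 with an estimated correlation). These included the cystine transporter gene SLC7A11 (3.08, SE 0.39), the serine synthesis gene PSAT1 (2.74, SE 0.43), ATF3 (2.54, SE 0.49) and the asparagine synthetase gene ASNS (2.36, SE 0.50). Immediate early genes rose in 9 of 15 cases, 12 when adjusted over the list alone (adjusted p = 0.051 with an estimated correlation). EGR1 was higher by 3.76 (SE 0.62) and CYR61 by 1.58 (SE 0.31). Oxidative stress genes rose in 6 of 17 cases, 7 when adjusted over the list alone (adjusted p = 0.0653 with an estimated correlation). These included the sulfiredoxin gene SRXN1 (2.44, SE 0.40). Scores of sepsis death replicates 1 to 4 were 1.31, 1.01, 4.12 and 3.17 for cytokines and 0.68, 0.72, 3.21 and 2.89 for NF-kB feedback, against 0.67 and 0.68 in low dose replicate 2. They were 0.49, 0.21, 2.06 and 1.31 for immediate early genes. Much of these rises lay in replicates 3 and 4, but not that of the acute phase list (2.31, 2.13, 1.63 and 1.75). The stress response score was 0.21 in sepsis death replicate 1 and 0.27 in low dose replicate 2.

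Markers of alveolar type 1 cells, the flat gas-exchange epithelium, fell in 8 of 12 cases, 10 when adjusted over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.0809 with an estimated correlation). CAV1, which endothelium also expresses, differed by -2.53 (SE 0.42), the tight junction gene CLDN18 by -1.76 (SE 0.32) and the water channel gene AQP4 by -2.63 (SE 0.48), with adjusted p from 0.0019 to 0.0032. Low dose replicate 5, the library of low ribosomal protein values, had an alveolar type 1 score of -0.44 and low dose replicate 2 a score of -0.17, against 0.56 to 0.83 in the other low-dose libraries and -1.10 to -0.79 in sepsis death. Nucleotide and polyamine genes rose in 5 of 18 cases, 5 up and 1 down when adjusted over the list alone (adjusted p = 0.051 with an estimated correlation). The purine and uridine phosphorylase genes PNP and UPP1 rose by 2.25 (SE 0.42) and 1.63 (SE 0.31). Genes of branched-chain amino acid and ketone metabolism fell in 3 of 18 cases, 8 when adjusted over the list alone (adjusted p = 0.052 with an estimated correlation). In the carnitine shuttle and beta-oxidation list, 7 of 35 genes fell and 2 rose, and 12 fell and 3 rose when adjusted over the list alone (adjusted p = 0.219 with an estimated correlation). The peroxisomal oxidase gene ACOX2 was lower (difference -1.35, SE 0.28).

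Interferon-stimulated genes passed the list test in sepsis death against low dose with 2 of 19 genes higher, 8 when adjusted over the list alone (adjusted p = 0.171 with an estimated correlation). Interferon-gamma response and antigen presentation genes rose in 3 of 13 cases, 7 when adjusted over the list alone (adjusted p = 0.219 with an estimated correlation). Scores of the latter list were -0.07, 0.25, 1.76 and 2.7 in sepsis death replicates 1 to 4, and 1.46 in low dose replicate 2. Those of the interferon-stimulated list were -0.08, 1.1, 0.7 and 1.84 in the same order, and 1 in low dose replicate 2. Pattern recognition and LPS sensing genes rose in 4 of 17 by either adjustment (adjusted p = 0.171 with an estimated correlation). Their score was 1.16 in low dose replicate 2, above the 0.8, 0.07, 0.88 and 0.94 of sepsis death replicates 1 to 4, and 0.03 in low dose replicate 5. Of 21 coagulation and fibrinolysis genes 5 rose and 1 fell, 7 and 2 when adjusted over the list alone (adjusted p = 0.159 with an estimated correlation). The urokinase receptor gene PLAUR was higher by 2.41 (SE 0.44). In the complement list, 1 gene of 17 rose and 1 fell, 5 and 2 when adjusted over the list alone (adjusted p = 0.311 with an estimated correlation), and the anaphylatoxin receptor gene C3AR1 was higher by 2.23 (SE 0.46). The erythroid and platelet list had 1 higher gene of 10 over all genes and over the list alone, TREML1 of platelet granules (2.89, SE 0.52; adjusted p = 0.219 with an estimated correlation). The club and secretory epithelium list had 0 of 7 (adjusted p = 0.105 with an estimated correlation). In the B and plasma cell list, 1 gene rose and 2 fell of 15, 2 and 2 when adjusted over the list alone, and the plasma cell receptor gene TNFRSF17 was lower (-1.14, SE 0.25). The monocyte and macrophage list had 1 higher gene of 14 by either adjustment, LILRB2 (2.77, SE 0.60). Glycolysis had 1 of 16 by either, the glucose transporter gene SLC2A3 (2.12, SE 0.33), heat shock 1 of 13 by either, and cell cycle 0 of 27 by either. For these lists adjusted p lay between 0.337 and 0.624 with an estimated correlation. The B and plasma cell call ended without low dose replicate 1, 2, 3, 4 or 6 or sepsis death replicate 1 or 2. Those of glycolysis and monocytes and macrophages ended without sepsis death replicate 1 or 2, that of cell cycle without sepsis death replicate 1, and that of heat shock without sepsis death replicate 3, with adjusted p of up to 0.46.

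The list of glucocorticoid-responsive genes was not called in sepsis death against low dose (camera adjusted p = 0.076; adjusted p = 0.58 with an estimated correlation), and its members went both ways. Of 18 genes 6 rose and 3 fell, 6 and 4 when adjusted over the list alone. GLUL and CEBPD rose by 1.32 (SE 0.28) and 1.90 (SE 0.45), and TSC22D3 (-1.61, SE 0.31) and KLF15 (-1.62, SE 0.33) fell. The call of CEBPD ended without sepsis death replicate 3 or 4 (adjusted p = 0.077 and 0.078), and that of GLUL without sepsis death replicate 4 (adjusted p = 0.054). Outside the called lists the kynureninase gene KYNU rose by 2.13 (SE 0.41). The soluble epoxide hydrolase gene EPHX2 fell (-1.30, SE 0.24), as did the prostaglandin D synthase gene PTGDS (-1.80, SE 0.36) and PPARG, a regulator of alveolar macrophages and lipid storage (-1.74, SE 0.34). VCAM1, an adhesion molecule of activated endothelium, rose by 2.68 (SE 0.52) and the protease gene ADAMTS4 by 4.86 (SE 0.94), while the tight junction gene OCLN fell (-1.34, SE 0.28).

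In all, 1702 of 17476 genes differed between sepsis death and low dose, 492 higher and 1210 lower (limma, adjusted p under 0.05). With each library centred on its median the split was 819 higher and 671 lower, with quantile normalisation 801 and 820, and with totals that leave out mitochondrial and small RNA loci 624 and 944. Without both libraries of low ribosomal protein values, low dose replicate 5 and high dose replicate 3, 3412 genes differed, and 5730 with array weights. The count was 591 without sepsis death replicate 3, 495 without replicate 4, 2883 without low dose replicate 5, and 1083, 1101 and 1093 without low dose replicates 3, 4 and 6. In 17 of the 23 called lists the scores of sepsis death and low-dose libraries overlapped, and in 9 with low dose replicates 2 and 5 set aside. In each of the 50 genes named here every sepsis death library lay on the called side of the low-dose mean, which the calling and picking of these genes favours. Apart from GLUL and CEBPD these were picked with their stability in view, and 48 passed with any single library left out. Of the 43 further called genes that the naming rule takes and that are not named, 2 did, so the named genes are not typical of the comparison.

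**Figure D2:**
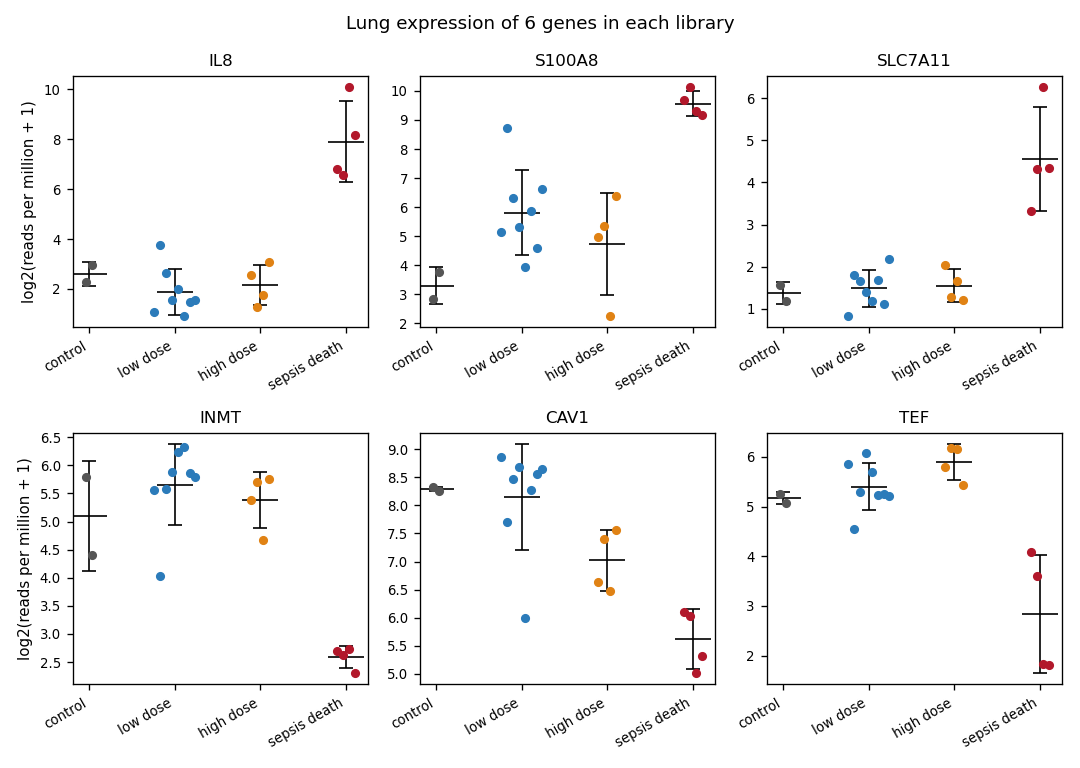
Expression of 6 genes in log2(RPM + 1) (y axis) by group, 1 point per library with the group mean and SD as bars. IL8, S100A8 and SLC7A11 lie higher in the 4 sepsis death libraries than in every other library, and INMT lies lower, with a sepsis death mean of 2.59.

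Sepsis death was compared with high-dose challenge to ask how these samples differed from the high-dose group. Inflammatory genes were higher in sepsis death. IL8 differed by 5.75 (SE 0.67, adjusted p = 0.00028), from 2.16 ± 0.80 (SD, n = 4) to 7.91 ± 1.61 (SD, n = 4), IL6 by 5.13 (SE 0.85) and CCL3 by 4.64 (SE 0.66). The largest rises among abundant genes with no overlap were in SOD2 (4.88, SE 0.69), S100A8 (4.83, SE 0.83) and TNFAIP3 (4.12, SE 0.74). The interferon-induced GTPase gene GBP1 rose by 3.64 (SE 0.93), but is uncertain because of an overlapping gene. The apoptosis inhibitor gene BIRC3 (3.5, SE 0.49) and PLEK, the main protein kinase C substrate of platelets (3.41, SE 0.80), rose as well. The largest falls were in TEF (-3.06, SE 0.43), INMT (-2.79, SE 0.41), the small nucleolar RNA SNORD17 and ATP6V0E1 (-2.77, SE 0.59 and -2.58, SE 0.53, both uncertain because of overlapping genes), and the heparan sulphate proteoglycan gene AGRN (-2.56, SE 0.50). The scaffold gene SLC9A3R2 fell as well (-2.47, SE 0.44). All of these had adjusted p of at most 0.02. GBP1 and PLEK lost their calls without high dose replicate 3 or sepsis death replicate 3 or 4, with adjusted p of up to 0.08.

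Inflammatory cytokine and chemokine genes rose in 12 of 16 cases against high dose, 13 when adjusted over the list alone (camera adjusted p = 6.42e-10; adjusted p = 0.355 with an estimated correlation). NF-kB feedback genes rose in 8 of 17 cases, 11 when adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). TNIP3 was higher by 4.08 (SE 0.53). Interferon-stimulated genes rose in 10 of 19 cases, 14 when adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). These included IFIT5 (2.22, SE 0.45). Acute phase and iron handling genes rose in 7 of 11 cases, 9 when adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). These included the ferroxidase gene CP (2.54, SE 0.50) and S100A9 (2.96, SE 0.65). Neutrophil markers rose in 8 of 21 cases, and 10 rose and 1 fell when adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). These included VNN2 (2.71, SE 0.53). In the coagulation and fibrinolysis list, 9 of 21 genes rose and 1 fell, 11 and 1 when adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). The platelet and matrix protein gene THBS1 was higher by 2.95 (SE 0.65) and the protease inhibitor gene TFPI2 by 3.07 (SE 0.67). Pattern recognition genes rose in 5 of 17 cases, 8 when adjusted over the list alone (adjusted p = 0.508 with an estimated correlation). These included IRAK3, a brake on Toll-like receptor signalling (1.98, SE 0.41), and the inflammatory caspase gene CASP5 (2.31, SE 0.50).

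Among stress and metabolic lists, the unfolded protein and integrated stress response rose in 5 of 15 cases against high dose, and in 15 when adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). SLC7A11 was higher by 3.02 (SE 0.45), PSAT1 by 2.79 (SE 0.50) and ASNS by 2.77 (SE 0.58). Oxidative stress genes rose in 6 of 17 cases, 7 up and 1 down when adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). These included SRXN1 (2.26, SE 0.46). Nucleotide and polyamine genes rose in 7 of 18 cases, 8 up and 1 down when adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). These included PNP (2.37, SE 0.48) and, with uncertain reads because of an overlapping gene, ARG2 (2.0, SE 0.27). Glucocorticoid-responsive genes rose in 5 of 18 cases and fell in 1, 6 and 1 when adjusted over the list alone (adjusted p = 0.549 with an estimated correlation). These included SGK1 (2.25, SE 0.48) and the metallothionein gene MT2A (4.15, SE 0.90). Of 13 interferon-gamma response and antigen presentation genes, 4 rose and 6 when adjusted over the list alone (adjusted p = 0.669 with an estimated correlation). Scores of this list were -0.07 and 0.25 in sepsis death replicates 1 and 2, below the 0.41 of high dose replicate 4, and 1.76 and 2.7 in replicates 3 and 4. Alveolar type 1 markers fell in 4 of 12 cases, and 7 fell and 1 rose when adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). SEMA3B was lower (-2.04, SE 0.40). Outside the called lists, the acyl-CoA synthetase gene ACSL1 rose by 2.45 (SE 0.37) and KYNU by 2.21 (SE 0.47), while the carnitine acetyltransferase gene CRAT (-1.67, SE 0.33), P4HA2 (-2.37, SE 0.34) and EPHX2 (-1.42, SE 0.28) fell.

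In all, 1955 genes differed between sepsis death and high dose, 1035 higher and 920 lower (limma), and 13 of 42 lists were called, 12 higher and 1 lower, with overlapping scores in 2, both interferon lists. The gene count was 2418 without both libraries of low ribosomal protein values, 732 and 1227 without high dose replicates 3 and 2, 644 and 562 without sepsis death replicates 3 and 4, and 3567 without low dose replicate 5. It was 409 in a fit of these groups alone, 495 with array weights and 1229 with library numbers 16 to 18 as a block. Array weights ended 6 of the calls of named genes, those of GBP1, S100A9, THBS1, VNN2, SGK1 and KYNU (adjusted p of up to 0.16), and the fit of these groups alone 5 (adjusted p of up to 0.073). In each of the 38 genes named here every sepsis death library lay on the called side of the high-dose mean, which the calling and picking of these genes favours. Of these 38, which were also picked with their stability in view, 36 passed with any single library left out, against 10 of the 39 further called genes that the naming rule takes. Mitochondrial reads made up 12% of the sepsis death and 2.96% of the high-dose libraries. At least as many lists were called in 17 of the 35 splits of these 8 samples, the real one included.

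Sepsis death was compared with the 2 baseline controls to ask how these lungs differed from unchallenged tissue. S100A8 averaged 9.56 ± 0.43 (SD, n = 4) in sepsis death and 3.30 ± 0.65 (SD, n = 2) in control, a difference of 6.26 (SE 1.01, adjusted p = 0.01). LCN2 differed by 6.63 (SE 1.20), HMOX1 by 5.73 (SE 1.03) and SOD2 by 4.69 (SE 0.84), and the overlapping genes TIMP1 and SYN1, whose reads cannot be told apart, by 4.97 (SE 1.07) and 4.89 (SE 1.06). The largest falls were in FMO2 (-3.50, SE 0.63), the sialyltransferase gene ST6GALNAC5 (-2.97, SE 0.68), COL4A4 (-2.83, SE 0.41), CAV1 (-2.67, SE 0.59), the desaturase gene SCD5 (-2.67, SE 0.40) and INMT (-2.51, SE 0.50). Adjusted p for these 12 genes lay between 0.0072 and 0.039. With control replicate 1 left out none of the 37 named genes that passed in this comparison did so, with adjusted p of up to 0.41, and with control replicate 2 left out none did, with adjusted p of up to 0.24. Without sepsis death replicates 3 and 4, 17 and 16 of them passed, without low dose replicates 3, 6 and 8, 27, 27 and 25, and without high dose replicate 2, 3 or 4, low dose replicate 1, 4 or 7 or sepsis death replicate 1, 31 to 36.

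Cytokine and chemokine genes rose in 10 of 16 cases against control, 12 when adjusted over the list alone (camera adjusted p = 8.27e-14; adjusted p = 0.0878 with an estimated correlation). CCL3 was higher by 5.44 (SE 0.81), IL8 by 5.31 (SE 0.82), IL6 by 6.11 (SE 1.04) and TNF by 3.96 (SE 0.76). Neutrophil markers rose in 9 of 21 cases, 15 when adjusted over the list alone (adjusted p = 0.075 with an estimated correlation). VNN2 was higher by 3.82 (SE 0.64), the growth factor receptor gene CSF3R by 3.89 (SE 0.68) and FPR2 by 3.76 (SE 0.60). Of 17 NF-kB feedback genes 7 rose and 16 when adjusted over the list alone, including ZC3H12A (3.64, SE 0.65), and of 11 acute phase and iron handling genes 4 and 7, including S100A9 (4.57, SE 0.80). For both lists adjusted p was 0.0878 with an estimated correlation. Oxidative stress genes rose in 5 of 17 cases and those of the unfolded protein and integrated stress response in 2 of 15, 7 and 10 when adjusted over the list alone. Branched-chain amino acid and ketone metabolism was lower as a list with 0 of 18 genes by either adjustment, and alveolar type 1 markers fell in 1 of 12 cases, 8 when adjusted over the list alone. These 4 lists also had adjusted p = 0.0878 with an estimated correlation. SLC7A11 was higher by 3.19 (SE 0.55), SRXN1 by 2.61 (SE 0.57) and ATF4, the transcription factor of the integrated stress response, by 1.67 (SE 0.39). CLDN18 differed by -1.64 (SE 0.46, adjusted p = 0.076) and did not pass. Of 18 nucleotide and polyamine genes 3 rose and 8 when adjusted over the list alone (adjusted p = 0.075 with an estimated correlation). These included AMPD3 (1.90, SE 0.41) and UPP1 (1.92, SE 0.44). Complement genes rose in 4 of 17 cases, 10 when adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). These included C1S (1.88, SE 0.42) and C3AR1 (2.87, SE 0.65). Each called gene named here lost its call without either control replicate, with adjusted p of up to 0.41.

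Further lists passed against control with fewer called genes, and their called genes also lost their calls without either control replicate, with adjusted p of up to 0.41. Immediate early genes rose in 3 of 15 cases, among them JUNB (3.42, SE 0.74) and MYC (2.67, SE 0.59). In pattern recognition 1 of 17 rose, MYD88 (1.95, SE 0.43), in glycolysis 1 of 16, SLC2A3 (2.26, SE 0.47), and in monocytes and macrophages 1 of 14, LILRB2 (3.47, SE 0.84). When adjusted over the list alone 9, 9, 5 and 4 rose in these lists. Their adjusted p lay between 0.148 and 0.389 with an estimated correlation. In the coagulation list 2 of 21 genes rose, THBS1 (3.68, SE 0.80) and PLAUR (2.64, SE 0.62), and 6 rose and 1 fell when adjusted over the list alone (adjusted p = 0.389 with an estimated correlation). In the glucocorticoid list 2 of 18 rose, CEBPD (2.84, SE 0.63) and GLUL (1.67, SE 0.40), and 7 rose and 1 fell when adjusted over the list alone (adjusted p = 0.501 with an estimated correlation). The interferon-stimulated list (0 of 19 genes, 6 when adjusted over the list alone) and the interferon-gamma list (0 of 13, 8 when adjusted over the list alone) passed as lists, with adjusted p of 0.269 and 0.195 with an estimated correlation. IFI35 differed by 1.83 (SE 0.46, adjusted p = 0.052), MX1 by 2.03 (SE 0.68, adjusted p = 0.13) and TAP1 by 2.59 (SE 0.71, adjusted p = 0.074). B and plasma cells were higher as a list (1 of 15 genes higher, and 6 higher and 1 lower when adjusted over the list alone). Cell cycle (27 genes), T and NK cells (22), club and secretory epithelium (7) and ciliated epithelium (12) were higher as lists with 0 genes by either adjustment. Endothelium was lower (0 of 20 genes, 2 lower when adjusted over the list alone). For these lists adjusted p lay from 0.11 to 0.58 with an estimated correlation. In the endothelial list TMEM100 differed by -3.49 (SE 0.99, adjusted p = 0.083) and the angiopoietin receptor gene TEK by -2.50 (SE 0.78, adjusted p = 0.11). List calls ended without control replicate 1 for coagulation, glucocorticoid-responsive genes and T and NK cells (adjusted p of up to 0.43), and without control replicate 2 for ciliated epithelium and endothelium (up to 0.32). They also ended without sepsis death replicate 3 for glucocorticoid-responsive genes, ciliated epithelium and endothelium (up to 0.17), without sepsis death replicate 4 for endothelium (up to 0.058) and without sepsis death replicate 1, high dose replicate 3 or low dose replicate 5 for coagulation (up to 0.056).

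In all, 238 genes differed between sepsis death and control, 177 higher and 61 lower (limma), and 754 without both libraries of low ribosomal protein values. The count was 1 and 0 without control replicates 1 and 2, and 611, 41 and 38 without sepsis death replicates 2, 3 and 4. It was 435 and 121 without high dose replicates 1 and 2, and 155, 409, 104, 142, 618, 107, 130 and 97 without low dose replicates 1 to 8. It was 78 with voom on recovered reads, 32 in a fit of these groups alone, 2543 with array weights and 25 with library numbers 16 to 18 as a block. The block ended 28 of the 37 calls of named genes (adjusted p of up to 0.16), those of LCN2, HMOX1, SOD2, FMO2, CAV1 and INMT among them. The fit of these groups alone also ended 28 (adjusted p of up to 0.2), IL8, IL6 and CCL3 among them, and voom 15 (adjusted p of up to 0.073). In 6 of the 24 called lists the scores of sepsis death and control libraries overlapped. In each of the 37 called genes every sepsis death library lay on the called side of the control mean, which the calling and picking of these genes favours.

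**Figure D3:**
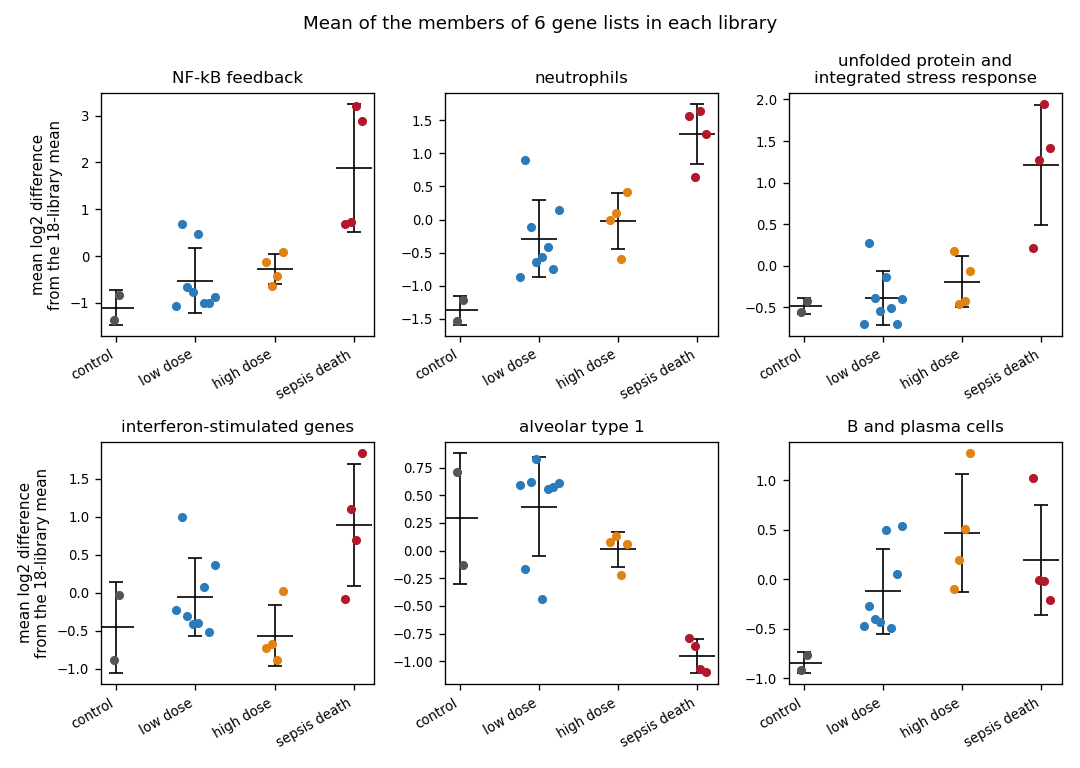
Mean over the members of 6 gene lists of each library's difference from the mean of the 18 libraries, in log2(RPM + 1) (y axis), by group, 1 point per library with the group mean and SD as bars. NF-kB feedback scores of sepsis death replicates 1 to 4 were 0.68, 0.72, 3.21 and 2.89, and low dose replicate 2 lay at 0.68.

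High-dose and low-dose challenge were compared to ask how the lung differed between these groups. Library order, as given above, cannot be told apart from the low-dose group. Genes of the NR4A family of early-induced nuclear receptors were higher in high dose than in low dose. NR4A3 averaged 5.66 ± 1.46 (SD, n = 4) in high dose and 2.41 ± 0.37 (SD, n = 8) in low dose, a difference of 3.25 (SE 0.57, adjusted p = 0.017). NR4A1 differed by 2.43 (SE 0.54) and NR4A2 by 2.51 (SE 0.69). In control NR4A3 averaged 6.03 ± 1.73 (SD, n = 2), NR4A1 4.88 ± 1.95 (SD, n = 2) and NR4A2 3.93 ± 1.54 (SD, n = 2). The scavenger receptor gene MARCO rose by 2.20 (SE 0.54), the binding protein gene IGFBP2 by 1.66 (SE 0.37), and CNKSR1 and JMY each by 0.80 (SE 0.23 and 0.19). Among the largest falls were TMTC2 (-4.01, SE 0.62, adjusted p = 0.0083), MEGF11 (-1.50, SE 0.28), UGGT2 of glycoprotein folding (-1.45, SE 0.27), FBXL13 (-1.37, SE 0.22) and ANKRD42 (-1.31, SE 0.26). Over all libraries TMTC2 went with the most abundant mitochondrial locus (Pearson r = 0.72, group differences included). Its fall was therefore not told apart from the lower mitochondrial reads. Mitochondrial reads made up 2.96% of the high-dose and 11.5% of the low-dose libraries. Of the 24 genes named in this comparison, 1, 7, 3 and 22 passed without high dose replicates 1 to 4, and 6, 19, 6, 5, 24, 5, 6 and 9 without low dose replicates 1 to 8. Between 20 and 23 passed without any single control or sepsis death replicate, with adjusted p of up to 0.057, against up to 0.19 without high dose replicate 1. NR4A3 was the gene that passed without high dose replicate 1, and it did not pass without high dose replicate 3.

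Immediate early genes rose in 3 of 15 cases in high dose against low dose, the NR4A genes above, and 6 when adjusted over the list alone (camera adjusted p = 2.2e-05; adjusted p = 0.995 with an estimated correlation). B and plasma cell genes rose in 2 of 15 cases, 6 when adjusted over the list alone (adjusted p = 0.995 with an estimated correlation), among them the B cell receptor component CD79B (2.21, SE 0.54). The erythroid and platelet list was higher with 2 of 10 genes up, the integrin gene ITGA2B (1.73, SE 0.39) and the platelet factor gene PF4 (1.18, SE 0.34), and 2 up and 1 down when adjusted over the list alone. The cell cycle list was higher with 0 of 27 genes by either adjustment. Both lists had adjusted p = 0.995 with an estimated correlation. The erythroid and platelet call ended without high dose replicate 2 or 4 or low dose replicate 5 (adjusted p of up to 0.33), and that of B and plasma cells without high dose replicate 4 (adjusted p of up to 0.15). In the carnitine shuttle and beta-oxidation list, 9 of 35 genes fell and 13 when adjusted over the list alone, including EHHADH (-1.32, SE 0.27), ACADSB (-1.05, SE 0.24) and ETFA (-0.75, SE 0.18). For this list fry gave an adjusted p of 0.00305 where camera gave 0.0791 (adjusted p = 0.995 with an estimated correlation). In branched-chain amino acid and ketone metabolism 3 of 18 fell by either adjustment, over all genes or adjusted over the list alone, including BCKDHB (-1.10, SE 0.26) and the methylmalonyl-CoA mutase gene MUT (-1.26, SE 0.34). The list had adjusted p of 0.0119 by fry and 0.49 by camera (adjusted p = 0.995 with an estimated correlation). Of the 4 lists that camera called here, fry kept 0 (fry adjusted p of up to 0.47). Unlike camera, fry does not set a list against the other genes, so the lower median gene in high dose (difference -0.19) enters its result. It was not run on centred values. The list of glucocorticoid-responsive genes was not called (camera adjusted p = 0.445; adjusted p = 0.995 with an estimated correlation). Of its 18 genes 4 fell, FOXO3 (-1.30, SE 0.28), PDK4 (-2.78, SE 0.66), ERRFI1 (-1.83, SE 0.53, uncertain because of an overlapping gene) and TSC22D3 (-1.04, SE 0.31), and 0 rose, while 6 fell and 1 rose when adjusted over the list alone. With each library centred on its median, 10 of the 24 genes named here lost their calls, the named genes of the carnitine and branched-chain lists among them (adjusted p of up to 0.093). As given above, the calls of these genes also ended without single libraries, with adjusted p of up to 0.19.

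In all, 1209 genes differed between high and low dose, 165 higher and 1044 lower (limma). Centring each library on its median gave 85 higher and 81 lower, quantile normalisation 99 and 119, and totals without mitochondrial and small RNA loci 63 and 150. Without both libraries of low ribosomal protein values the count was 4484, 1140 higher and 3344 lower. It was 204 in a fit of these groups alone, 679 with array weights and 169 with voom on recovered reads, and 9, 13 and 11 of the 24 named genes lost their calls in these fits (adjusted p of up to 0.11). It was 3, 59, 26 and 3353 without high dose replicates 1 to 4, 61, 547, 41, 33, 6016, 34, 40 and 94 without low dose replicates 1 to 8, and 715 and 716 without control replicates 1 and 2. In each of the 24 named genes every high-dose library lay on the called side of the low-dose mean, which the calling and picking of these genes favours. The scores of high-dose and low-dose libraries overlapped in each of the 4 called lists. Of the 42 lists 4 were called, and 6, 3, 14 and 2 without high dose replicates 1 to 4 and 7 without low dose replicate 2. Splits of these 12 samples gave at least 4 called lists in 82 of 100 draws, the real one included.

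Low-dose challenge was compared with baseline control. Higher as lists were neutrophil markers (camera adjusted p = 5e-06), T and NK cells, complement, alveolar type 2 and surfactant genes, ciliated epithelium and B and plasma cells. In these, 0 genes passed over all genes or when adjusted over the list alone (adjusted p from 0.74 to 0.772 with an estimated correlation). The complement factor gene CFB stood at 7.20 ± 0.59 (SD, n = 8) in low dose and 4.92 ± 0.20 (SD, n = 2) in control (difference 2.29, SE 0.73). C1R differed by 1.24 (SE 0.47), C1S by 1.17 (SE 0.38) and CSF3R by 2.12 (SE 0.62). MMP9 averaged 3.46 ± 1.34 (SD, n = 8) in low dose and 1.28 ± 0.43 (SD, n = 2) in control. The surfactant gene SFTPA1 differed by 1.59 (SE 0.61), CTSH by 1.23 (SE 0.41) and the perforin gene PRF1 by 1.61 (SE 0.64). IGJ differed by 1.93 (SE 0.88) and HYDIN of motile cilia by 1.22 (SE 0.49). Each of these had adjusted p = 1. Pattern recognition, interferon-gamma response, glycolysis, carnitine shuttle, cell cycle, and monocytes and macrophages were also higher as lists, again with 0 genes by either adjustment. Their camera adjusted p lay from 0.0203 to 0.0344, and adjusted p from 0.74 to 0.772 with an estimated correlation. HK3 differed by 1.77 (SE 0.71), the carnitine palmitoyltransferase gene CPT1A by 1.25 (SE 0.34) and C1QA by 1.65 (SE 0.85). Lower by the list test were immediate early genes, with 1 gene down when adjusted over the list alone and NR4A3 at a difference of -3.62 (SE 0.73, adjusted p = 1), endothelial activation and endothelium (adjusted p = 0.772 with an estimated correlation for each). In immediate early genes the median member differed by 0.10, opposite in sign to the test, and the mean by -0.27. The median and mean were -0.10 and -0.01 in endothelial activation, and 0.01 and 0.00, not below 0, in endothelium, against the shift of 0.19 over all genes. The neutrophil, T and NK cell, complement and alveolar type 2 lists passed with any single library left out. Of the 15 calls, 10 and 5 were kept without control replicates 1 and 2, the endothelium list turning to higher in the second case (adjusted p = 0.99), 13 without high dose replicate 1, and 14, 8, 11, 13 and 13 without low dose replicates 1, 2, 5, 7 and 8, with adjusted p of up to 0.99.

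No gene (0 of 17476) differed between low dose and control in limma at an adjusted p under 0.05, while 703 had an unadjusted p under 0.05. The count was also 0 with voom on recovered reads and without both libraries of low ribosomal protein values, 3 with array weights, 2 without low dose replicate 1 and 1 without control replicate 1. In 7 of the 15 called lists, pattern recognition, interferon-gamma response, glycolysis and cell cycle among them, the scores of low-dose and control libraries overlapped, and in 6 with low dose replicates 2 and 5 set aside. The number of called lists was 15, and 8 without low dose replicate 2 and 10 without control replicate 2, and fry called 0. Simulated changes, in either direction and in genes above the median mean, were recovered here for 10% of genes at a log2 change of 1 and 74% at 2. That simulation drew the spread independently for each gene, so these shares do not measure what the real test could find. No splits of the samples were made with the controls, so chance is not excluded for the number of lists. Other splits of the challenge groups gave medians of 11 and 12 called lists, but with other group sizes and libraries they set no chance level here.

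High-dose challenge was compared with baseline control in the same way. No splits of the samples were made with the controls. Other splits of the challenge groups gave medians of 11 and 12 called lists. With other group sizes and libraries they set no chance level for the 7 called here, and chance is not excluded for that number. Neutrophil markers were higher as a list (camera adjusted p = 0.000648; adjusted p = 0.938 with an estimated correlation), with 0 of 21 genes passing over all genes and 6 when adjusted over the list alone. MMP9, a matrix protease of neutrophil granules, averaged 4.76 ± 0.72 (SD, n = 4) in high dose and 1.28 ± 0.43 (SD, n = 2) in control (difference 3.48, SE 0.84, adjusted p = 0.12). The myeloperoxidase gene, MPO, differed by 3.18 (SE 0.88, adjusted p = 0.12). B and plasma cell genes were higher (0 of 15 genes, 6 when adjusted over the list alone; adjusted p = 0.938 with an estimated correlation). CD79B stood at a difference of 3.11 (SE 0.76) and PAX5 at 1.97 (SE 0.54). Cell cycle genes (0 of 27), glycolysis (0 of 16), alveolar type 2 genes (0 of 18), T and NK cells (0 of 22) and immediate early genes (0 of 15) were higher as lists, each with adjusted p = 0.938 with an estimated correlation. When adjusted over the list alone, 1, 1, 3, 3 and 2 of their genes passed. Scores of high-dose and control libraries overlapped in 2 of the 7 called lists: that of T and NK cells was -0.94 in high dose replicate 1 and -0.92 and -0.44 in the controls, and that of immediate early genes -0.27 in high dose replicate 2 and -0.05 in control replicate 2. RRM2 of the cell cycle list differed by 2.43 (SE 0.60) and the hexokinase gene HK3 by 2.78 (SE 0.78). The surfactant gene SFTPC differed by 1.60 (SE 0.51) and CTSH by 1.62 (SE 0.45). PRF1 and ZAP70 of T and NK cells differed by 2.13 (SE 0.70) and 1.62 (SE 0.51), and JUNB and IER2 by 2.29 (SE 0.74) and 1.95 (SE 0.59). The named genes of these lists had adjusted p of 0.12 or 0.13. Mitochondrial reads made up 2.96% ± 3.3 (SD, n = 4) of the high-dose libraries, and 16.68% and 13.22% of the controls. The neutrophil, B and plasma cell and cell cycle lists passed with any single library left out. The other calls ended without control replicate 1, high dose replicate 1, 3 or 4 or low dose replicate 5, with adjusted p of up to 0.27.

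No gene (0 of 17476) differed between high dose and control in limma at an adjusted p under 0.05, against 4232 at an unadjusted p under 0.05. With voom on recovered reads the count was also 0. A fit of these groups alone gave 30 and one with library numbers 16 to 18 as a block 81. The count was 1310 without both libraries of low ribosomal protein values, 2087 without low dose replicate 5 and 2 without control replicate 1. The number of called lists was 7, and 3 without control replicate 1, 4 without high dose replicate 1 and 4 without low dose replicate 5, and fry called 0.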

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

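Of 402 sets of values tested within a group for a single library apart from the others, 31 held one, and chance alone gives about 1 in 20. Low dose replicate 2 held 13 of them and low dose replicate 5 held 9. The tests of a swap, of scaling and of read depth below were chosen only after the result was seen.

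Low dose replicate 2 stood apart within its group. It was higher than the other low-dose libraries in C1R (8.08, others 6.27 to 7.06), C3AR1 (5.76, others 3.06 to 4.16), MARS (5.73, others 4.69 to 5.16), S100A9 (9.89, others 6.09 to 7.41), SOD2 (6.69, others 2.95 to 3.86) and YARS (5.71, others 4.47 to 4.92), and lower in DKK3 (4.44, others 6.18 to 7.18) and INMT (4.03, others 5.56 to 6.32). Its list scores were higher for pattern recognition and LPS sensing (1.16), interferon-gamma response (1.46), acute phase and iron handling (1.32), oxidative stress (0.61) and monocytes and macrophages (1.61), against at most 0.03, 0.29, -0.29, 0.01 and 0.10 in the others. A swap with a sepsis death library would leave a partner out of place, and 0 of the 4 sepsis death libraries had their highest correlation outside sepsis death with this library set aside. A wrong label of this library alone cannot be told apart from a strong response in it: it lay nearer to the sepsis death mean for 47% of the genes that part the groups, far above the 1.8% to 8.2% of the 6 low-dose libraries other than replicate 5 and below the 55.4% to 93.9% of left-out sepsis death libraries. Low dose replicate 5, at 55.4%, reached the range of sepsis death too, which keeps the question open. No biological explanation was tested for this library.

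Low dose replicate 5 was lower than the other low-dose libraries in CAV1 (5.99, others 7.71 to 8.86), ETFA (5.14, others 5.55 to 5.80), FOXO3 (7.44, others 8.20 to 8.71), MUT (3.06, others 4.02 to 4.51), PDK4 (3.72, others 5.48 to 6.43) and TMTC2 (10.44, others 11.87 to 12.89). Its mitochondrial share was 3.1% (others 9.63% to 14.77%), its mean over ribosomal protein genes 5.84 (others 7.07 to 7.41) and its ribosomal protein score -1.04 (others 0.19 to 0.53). UGGT2 was lower in low dose replicate 1 (4.80, others 5.47 to 6.03) and MEGF11 in high dose replicate 1 (2.52, others 3.67 to 3.89).

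Most genes that changed between high and low dose were lower in high dose, 1044 of 1209 over all genes. Scaling of whole libraries cannot be told apart from a difference of these genes: with totals that leave out mitochondrial and small RNA loci 70.4% of 213 calls were lower, against 86.4%. Centring each library on its median evens the split by its construction, so the 48.8% found with it decides nothing. The libraries of low ribosomal protein values, low dose replicate 5 and high dose replicate 3, are not needed for lower calls, since 3344 were made without both of them. Higher calls rose as well, to 1140, so this count does not decide whether these libraries shape the share of lower genes. The dose itself and library order stay open as untested explanations.

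Sepsis death libraries fell into pairs, 3 and 4 against 1 and 2, and 933 genes parted them by at least 2 in log2, 763 higher and 170 lower in 3 and 4, with a median of 2.58. Read depth is argued against, since replicate 4 had 9.1 M reads, more than replicates 1 and 2, although replicate 3 had the lowest depth of the group (3.52 M, others 8.41 to 9.10). A batch of library numbers 16 to 18 cannot be told apart: high dose replicate 4, number 16, differed from its group over the same genes with a median of 0.10, but the quartiles ran from -0.44 to 0.81. RNA quality as in low dose replicate 5 cannot be told apart either, with a median of 0.61 and quartiles from -0.03 to 1.33. Time of sampling and bacterial number are not given in the labels and were not tested. Within sepsis death, ASNS was lower in replicate 1 (2.96, others 5.30 to 5.44) and SCD5 (5.07, others 3.84 to 4.03) and the B and plasma cell score (1.02, others -0.21 to -0.01) were higher there. IRAK3 (6.4, others 7.09 to 7.15) and the pattern recognition score (0.07, others 0.80 to 0.94) were lower in replicate 2, and MYC higher in replicate 3 (7.51, others 5.11 to 5.51).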

How the results depend on the processing

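The alternatives with voom, both libraries of low ribosomal protein values left out, totals without mitochondrial and small RNA loci, genes with few shared reads and a block were chosen after seeing the data. The pseudocount alternative was not run, since the values were deposited on a log scale. No paired analysis was possible because the labels give no replicate numbers. Where a count or call changed, the cause was not tested, except that leaving out libraries lowers the number of samples.

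The count of genes changed in low dose against control (0) was 3 with array weights. That of high dose against control (0) was 30 with only the compared groups, 1310 without both libraries of low ribosomal protein values and 81 with library numbers 16 to 18 as a block. That of sepsis death against control (238) was 2543 with array weights, 32 with only the compared groups, 78 with voom, 754 without both libraries and 25 with the block. That of high against low dose (1209) was 166 with median centring, 218 with quantile normalisation, 679 with array weights, 204 with only the compared groups, 169 with voom, 4484 without both libraries and 213 with totals that leave out mitochondrial and small RNA loci. That of sepsis death against low dose (1702) was 5730 with array weights and 3412 without both libraries. The block was fitted only for comparisons without low dose, so it was not run for this count. That of sepsis death against high dose (1955) was 495 with array weights, 409 with only the compared groups and 1229 with the block. Array weights ran from 0.014 in high dose replicate 2 and 0.19 in low dose replicate 5 to 5.3 in low dose replicate 4, so that fit nearly leaves a library out.

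With each library left out in turn, the counts of genes ran from 0 to 2 for low dose against control, 0 to 2087 for high dose against control, 0 to 618 for sepsis death against control, 3 to 6016 for high against low dose, 495 to 2883 for sepsis death against low dose and 562 to 3567 for sepsis death against high dose. A group left with 1 control is assumed to vary like the other groups. Called lists ran from 8 to 15, 3 to 9, 23 to 26, 2 to 14, 19 to 23 and 13 to 15 in the same order. With an estimated correlation 0 lists were called in each of the 6 comparisons. fry called 0 lists for low dose against control, 0 for high dose against control, 14 for sepsis death against control, 2 for high against low dose, 11 for sepsis death against low dose and 12 for sepsis death against high dose.

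Of the 157 calls of named genes, 10 were lost with median centring, 9 with quantile normalisation, 1 without a trend, 19 with array weights, 42 with only the compared groups, 26 with voom, 2 without both libraries, 12 with totals that leave out mitochondrial and small RNA loci and 28 of 75 with the block, all against control, and 69 were lost in at least 1 fit with a library left out. Of those tested, 0 of 136 were lost with the filter and 0 of 149 among genes with few shared reads. Most of these genes were picked with their stability in view: over all called genes that the naming rule takes, 50 of 93 for sepsis death against low dose, 46 of 77 against high dose, 0 of 44 against control and 0 of 31 for high against low dose passed with any single library left out. No named gene reversed in these fits. Of the 86 list calls, 49 were lost with fry, 8 without both libraries, 6 with median centring, 5 with totals that leave out mitochondrial and small RNA loci, 6 among genes with few shared reads, 4 of 44 with the block and 27 in at least 1 fit with a library left out. The endothelium list in low dose against control reversed with fry (adjusted p = 0.96) and without control replicate 2 (adjusted p = 0.99), and its adjusted p was 0.0013 without control replicate 1. Depth limits genes of few reads most in sepsis death replicate 3, where 1 read is worth 0.284 RPM, against 0.0881 in control replicate 1.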

Other observations

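Genes of the circadian clock and cytosolic aminoacyl-tRNA synthetases were looked at as sets only after their values were seen, and so were CNN3 and TMTC2. In sepsis death against low dose, 6 of 16 clock genes fell and 2 rose. Besides TEF, the PAR bZIP factor HLF fell from 5.28 ± 0.46 (SD, n = 8) to 3.71 ± 0.31 (SD, n = 4), a difference of -1.56 (SE 0.25, limma adjusted p = 0.0015), and the clock repressor gene CRY2 by a difference of -1.19 (SE 0.20, adjusted p = 0.0019). DBP, uncertain because of an overlapping gene, differed by -1.36 (SE 0.31, adjusted p = 0.011), and NFIL3, a repressor that binds the sites of PAR bZIP factors, by 1.43 (SE 0.34, adjusted p = 0.014). Against high dose 4 clock genes fell and 1 rose. The call of NFIL3 ended without sepsis death replicate 3 (adjusted p = 0.082) and that of DBP without sepsis death replicate 4 (adjusted p = 0.056). Time of day of sampling is not given in the labels.

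Aminoacyl-tRNA synthetases, which charge tRNAs and several of which are known targets of ATF4, rose in 6 of 16 measured cases in sepsis death against low dose, with 0 lower, and in 6 of 16 against high dose. GARS differed by 1.89 (SE 0.34, limma adjusted p = 0.0029), YARS by 1.39 (SE 0.28, adjusted p = 0.0048), MARS by 1.08 (SE 0.26, adjusted p = 0.014) and SARS by 1.16 (SE 0.29, adjusted p = 0.017) against low dose. The calls of MARS and SARS ended without sepsis death replicate 3 (adjusted p = 0.077 and 0.081) or 4 (adjusted p = 0.07 for both).

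CNN3 and TMTC2 were set against the most abundant mitochondrial locus because both were low in the high-dose libraries, where that locus is low too. Over the 18 libraries Pearson r was 0.91 for CNN3 (permutation p = 2e-05, adjusted p = 8e-05) and 0.72 for TMTC2 (permutation p = 0.00051, adjusted p = 0.00068), and Spearman rho 0.76 (permutation p = 0.00043, adjusted p = 0.00068) and 0.65 (permutation p = 0.0043, adjusted p = 0.0043; 4 coefficients tested). Without high dose replicates 1 and 3 r was 0.81 and 0.52. These values include the differences between groups. With each value less its group mean, and permuted within groups, CNN3 had r = 0.83 (permutation p = 0.0026, adjusted p = 0.01) and rho = 0.47 (permutation p = 0.064, adjusted p = 0.085). TMTC2 had r = 0.42 (permutation p = 0.029, adjusted p = 0.058) and rho = 0.36 (permutation p = 0.14, adjusted p = 0.15), so neither coefficient passed in this test. Within low dose alone CNN3 had r = 0.98 (permutation p = 0.002, adjusted p = 0.01) and rho = 0.76 (permutation p = 0.037, adjusted p = 0.059). TMTC2 had r = 0.94 (permutation p = 0.014, adjusted p = 0.037) and rho = 0.57 (permutation p = 0.15, adjusted p = 0.15) there. Without low dose replicates 3 and 5 these r were 0.65 and 0.49, so the low-dose relations rest on those libraries, and 8 coefficients were tested within groups.

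Other splits of the same samples were counted for each comparison of groups of at least 3. For sepsis death against low dose, 1 of 100 splits drawn from 495, the real one, gave as many genes (1702, highest other 83). The number of genes was thus far above that of the other splits drawn. Chance is not called excluded, since not all splits were drawn and separate animals are not stated. As many lists were called in 4 of 100 (23, highest other 23, median of the others 11). That share is under 0.05, but other splits reached the same number, so chance is not taken as excluded for the lists. For sepsis death against high dose, 1 of the 35 splits, the real one, gave as many genes (1955, highest other 652). In 17 of 35 as many lists were called (13, highest other 24, median of the others 12), so chance is not excluded for the number of lists. For high against low dose, 4 of 100 splits drawn from 495 gave as many genes (1209, highest other 4380). That share too is under 0.05, but with other splits as large chance is not taken as excluded. A split that set high dose replicates 1 and 3 and low dose replicates 2 and 5 against the rest gave the highest count, several times the real one. What these libraries might share was not tested. As many lists were called in 82 of 100 splits (4, highest other 31, median of the others 11), so chance is not excluded for the number of lists there. Comparisons with the controls had no such splits. Their groups have other sizes and libraries, so these medians set no chance level for them, and chance is not excluded for their numbers of called lists.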
